A study of Arabidopsis thaliana with 24 samples.

How the data were processed

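Per the labels' protocols, total RNA was extracted with a Qiagen kit, and mRNA libraries made with standard Illumina protocols were sequenced on an Illumina HiSeq 2000. Per the submitters' processing notes, reads were handled with TopHat and Cufflinks on the TAIR10 genome build; the versions and settings are not given in the sources used here. The authors deposited 6 tables, one per pair of groups. Each table held 33557 genes with 1 value per group, the log2 ratio of both values, a test statistic, a p-value, a q-value and a test status. The header does not name the unit of the group values, so FPKM was taken from the column layout of the authors' tables and the Cufflinks label. The deposited log2 column equalled the log2 ratio of the 2 group values wherever both were above 0. Values of single samples were not in the deposited tables used here, so no spread between samples was computed. Neither read counts nor depths per sample are given in the sources used here, so the depth behind each value is unknown.

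A gene was called where the authors' deposited q-value was under 0.05 and the deposited test status was OK. The standard error (SE) of a log2 fold was recovered as the absolute log2 fold over the absolute test statistic of the authors' table. It therefore describes the authors' model, and the 3 samples of a group, which the labels call biological repeats, enter only through it. The light tables and the mutant tables had been tested in different ways. In the deposited light tables the smallest p-value was 5e-05, shared by 1450 genes in cotyledons at 1 h, 4202 in cotyledons at 6 h, 1315 in hypocotyls at 1 h and 3944 in hypocotyls at 6 h. The median ratio of the normal score of the authors' p-value to the statistic was 1.69, 1.68, 1.67 and 1.66 in these tables and 1 in both mutant tables. A call of the light tables is thus less strict, for the same statistic, than a call of the mutant tables, and the numbers of calls were not compared between them. The deposited q-value of the mutant tables was the Benjamini-Hochberg adjustment over their tested genes, whereas that of the light tables was not the adjustment over each table alone. The statistic of the mutant tables had the opposite sign to their log2 column, and directions were read from the group values.

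The response of a gene was compared between organs by the difference of the cotyledon and hypocotyl log2 folds over the root of the summed squared SEs. A two-sided normal p was adjusted by Benjamini-Hochberg over the genes tested in both tables of the contrast, and genes under 0.05 are said to differ. The organs share no sample. In simulated data with known changes, this test found 1.5% of differences of 1, 31.7% of differences of 2 and 81.2% of differences of 3 on the log2 scale at 1 h. At 6 h it found 3.2%, 28.8% and 58.3%, and in the mutant contrast 8.5%, 49.3% and 88.7%. The simulation changed 200 genes per contrast, fewer than differed at 6 h and in the mutant contrast, where the adjustment is less strict. The shares found may therefore be too low for those contrasts. Unchanged genes called were 5 of 16159 simulated genes at 1 h, 0 at 6 h and 7 of 16794 in the mutant contrast. Noise was drawn with the recovered SEs, so these calls cannot show whether those SEs are right.

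Before the data were examined, 21 gene lists with 535 genes were fixed. They were the SAUR family, photosynthesis, chlorophyll synthesis, early auxin response (Aux/IAA and GH3), auxin synthesis and transport, cell wall loosening (expansins and XTHs), flavonoid synthesis, light signalling, dark and shade induced genes, circadian clock, and cell cycle and DNA replication. The others were cytosolic ribosomal proteins, gibberellin and brassinosteroid, ethylene and apical hook, heat and abiotic stress, wounding with touch and jasmonate, shoot meristem and leaf primordium markers, root markers, seed storage and lipid reserve, stomatal lineage markers, and the PIF genes. Counts within a list were repeated with the p-value adjusted over the list alone. The median log2 fold of a list was placed among 10000 random lists of the same size matched on FPKM in 10 bins; percentile 0 or 100 means below or above practically all of them. Medians and percentiles cover the tested members of a list unless all members are named. These percentiles describe a list and are not tests across samples.

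Genes were named by a rule fixed before the data were examined. It took PIF1, PIF3, PIF4 and PIF5 in the mutant comparisons and, per comparison, the 6 largest rises and the 6 largest falls among called genes with at least 5 FPKM in the higher group. It also took up to 2 risen and 2 fallen members per list with at least 1 FPKM in the higher group. From the organ contrasts it took up to 6 SAUR genes called in opposite directions at each time, and the 4 genes of smallest p in each direction with at least 5 FPKM in one group. Near copies are named as such. Positions are those of the TAIR10 annotation. Of the gene identifiers in the authors' tables, 32810 were matched to names. The tables gave 4249 genes a locus shared with another gene, and genes with a transcript at least 90% identical to another over at least 50% of its length are called near copies, since reads could be shared between them.

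Alternatives fixed beforehand were a q-value under 0.01, a change of at least 2-fold, at least 1 FPKM, folds centred on the median gene, a normal p from the statistic, an SE recovered from the p-value, a pseudocount of 1 FPKM, and adjustment over the list alone. Centring with the SE from the p-value, genes with a locus of their own, and SAUR genes without near copies were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9, and near copies were found with BLAST 2.17.0.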

Results

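RNA of Arabidopsis thaliana seedlings was measured by sequencing in cotyledons, the seed leaves, and in hypocotyls, the seedling stem. The series comprised 24 samples in 8 groups of 3. Wild type seedlings were grown in the dark for 4 days and harvested in the dark or after 1 h or 6 h of white light at 70 µmol per square metre and second. Both organs were collected separately at each point, which gave 6 wild type groups and 18 wild type samples. The other 2 groups were dark-grown cotyledons and hypocotyls of a line labelled pifq, a name used for plants mutated in the transcription factor genes PIF1, PIF3, PIF4 and PIF5. Before the dark period, germination had been started with 3 h of white light, followed by 5 min of far-red light at 2 µmol per square metre and second. The labels call the 3 samples of a group biological repeats, but the authors deposited 1 FPKM value per group, so each FPKM below is the authors' group value, and p-values and SEs come from the authors' statistic. The title of the series asks how SAUR genes, a family of small auxin-induced transcripts, take part in the different light regulation of organs.

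The authors' deposited tables tested 18998 to 20441 of 33557 genes. Some of the most abundant transcripts, among them LHCB1.3 and RBCS1A in cotyledons and CAT3 in hypocotyls, had been left untested there as too abundant. The mutant tables hold wild type columns of their own. Over 12325 genes in cotyledons and 12606 genes in hypocotyls with over 5 FPKM, the log2 ratio of these columns to the dark columns of the light tables had a median of 0.09 and 0.08 and an SD over genes of 0.20 and 0.19. The labels link the dark samples to the light tables alone, so the identity of the samples behind those wild type columns rests on these values. Cotyledon and hypocotyl values stand in separate tables, so FPKM are compared within an organ except in the closing section, where the scale between tables is not known. In the comparisons that follow, genes that rose or fell are those called by the q-value of the authors' deposited table, and their sizes are log2 folds.

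**Figure D1:**
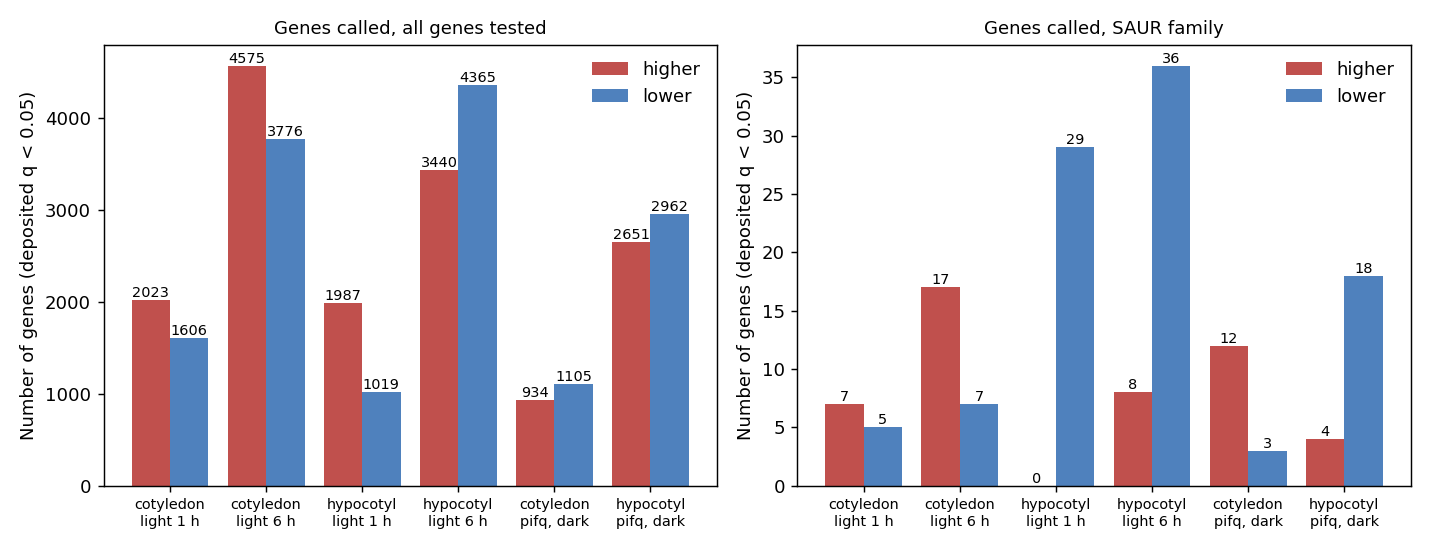
Bars give the number of genes called higher (red) or lower (blue) at the authors' deposited q-value under 0.05 in each of the 6 comparisons, for all genes tested on the left and for the SAUR family on the right. Among the SAUR genes called in cotyledons, 7 were higher and 5 lower at 1 h of light, and 17 were higher and 7 lower at 6 h, with 34 not called. In hypocotyls at 6 h, 36 were lower and 8 higher, with 21 not called. All genes went both ways in both organs.

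The first question was what 1 h of light changed in cotyledons. The largest rise among named genes was that of BBX32 (AT3G21150, chromosome 3, 7412636 to 7413539), for a B-box regulator of light responses, which went from 1.65 to 258 FPKM, a log2 fold of 7.29 (SE 0.67). It was followed by AT3G44450, of unknown function, with 6.87 (SE 1.25), the B-box gene BBX30 with 6.47 (SE 0.89), AT5G42760, for a methyltransferase family protein and sharing its locus with another gene, with 6.16 (SE 1.44), and BBX31 with 5.86 (SE 0.85). The thionin gene THI2.2 rose by 5.69 (SE 0.74). SAUR17 (AT4G09530, chromosome 4, 6029413 to 6029724), an abundant SAUR transcript of dark cotyledons, fell from 139 to 4.23 FPKM, a log2 fold of -5.03 (SE 0.95). The transcription factor genes RAV1 and GRF7 fell as well, with log2 folds of -4.41 (SE 0.39) and -4.03 (SE 0.40).

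Among 31 light signalling genes tested, 20 rose and 5 fell. SIG5, for a chloroplast sigma factor, rose by 4.85 (SE 0.39) and BBX25, which shares its locus with another gene, by 4.24 (SE 0.52), while BBX23 fell by 3.76 on the log2 scale. Of 21 circadian clock genes 18 rose, or 19 adjusted over the list alone, led by PRR9 with 4.08 (SE 0.49) and LNK1 with 2.99 (SE 0.40). Of 20 flavonoid synthesis genes 15 rose, with a median log2 fold over the list of 2.02; the regulator MYB12 went from 0.234 to 8.42 FPKM. Of 15 heat and abiotic stress genes 8 rose, among them HSFA2 with 2.78 (SE 0.50) and DREB2A with 2.21 (SE 0.38). Of 16 genes known as induced in dark and shade, 12 fell, including PAR1 with -3.78 (SE 0.53) and the cell wall gene XTH15, which went from 1915 to 191 FPKM; adjusted over the list alone 1 member also rose.

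Of 55 SAUR genes tested in cotyledons at 1 h, 7 rose and 5 fell, both over all genes and adjusted over the list alone. SAUR14 (AT4G38840, chromosome 4, 18124978 to 18125559) rose from 13.2 to 129 FPKM and SAUR35 from 0.481 to 2.81 FPKM. SAUR54 fell from 15.9 to 2.41 FPKM. Of 17 auxin synthesis and transport genes 10 fell and 1 rose, or 11 and 2 adjusted over the list alone; the auxin importer gene AUX1 fell from 70.1 to 21.8 FPKM. Among 33 early auxin response genes 9 rose and 7 fell, with GH3.6 up by 2.35 (SE 0.47) and IAA20 at -1.84 (SE 0.39). Expansin and XTH genes, for cell wall loosening, divided into 7 up and 7 down of 39, with EXPA1 up by 1.94 (SE 0.41). Gibberellin and brassinosteroid genes divided into 7 up and 5 down of 31, and GAI fell from 17.7 to 5 FPKM.

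Of 50 photosynthesis genes 10 rose in cotyledons by 1 h, and the median of the list was 0.09. Of 25 chlorophyll synthesis genes 4 rose and 3 fell, with CHLH up by 1.31 (SE 0.55) and PORB, abundant in the dark, down from 2424 to 1128 FPKM. Of 34 cell cycle and DNA replication genes 4 rose and 1 fell, or 3 and 1 adjusted over the list alone. Of 28 cytosolic ribosomal protein genes 3 rose over all genes; adjusted over the list alone the count was 0, and 4 had an unadjusted p under 0.05. In the ethylene and apical hook list 1 of 18 rose and 4 fell, or 0 and 3 adjusted over the list alone (2 rose at an unadjusted p under 0.05), and HLS1, needed for the apical hook, fell from 30.4 to 3.34 FPKM. Of 15 wounding, touch and jasmonate genes 3 rose and 1 fell; 2 of 7 seed storage genes fell, 1 of 10 shoot meristem and leaf markers fell, and 1 of 6 stomatal lineage markers rose. Among the PIF genes, PIF5 rose while PIF3 and PIF1 fell, and none of the 8 root markers was tested. In the authors' deposited table, 2023 genes rose and 1606 fell of 18998 tested. With folds centred on the median gene and a normal p from the statistic, 664 rose and 372 fell, and 3 SAUR genes rose. The number of SAUR genes that fell stayed within 1.5 times of 5 there, so the rises no longer outnumbered the falls.

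After 6 h of light the question in cotyledons was the same for the later response. Many genes for photosynthesis, ribosomes and cell division rose, and SAUR genes rose more often than they fell. SAUR16 (AT4G38860, chromosome 4, 18130268 to 18131060) went from 1.2 to 60.1 FPKM, a log2 fold of 5.64 (SE 0.69), and SAUR14 reached 337 FPKM. Of 58 SAUR genes tested, 17 rose and 7 fell, or 18 and 7 adjusted over the list alone, and the median of the tested members, 1.11, stood at percentile 100 of random lists matched on FPKM; over all 78 members, with a pseudocount of 1 FPKM, the median was 0.17. SAUR54 and SAUR55 fell, with log2 folds of -3.85 (SE 0.77) and -3.07 (SE 0.77).

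Of 50 photosynthesis genes 47 rose, or 48 adjusted over the list alone, with a median of 1.59; LHCB1.1 and LHCB1.4 rose by 4.34 (SE 0.62) and 3.73 (SE 0.54), but both are near copies of related genes. Of 25 chlorophyll synthesis genes 15 rose and 3 fell: GUN4 rose from 317 to 873 FPKM, and PORA, the light-sensitive reductase of dark-grown seedlings, fell from 2809 to 34.8 FPKM. Of 28 ribosomal protein genes 26 rose, with a median of 1.13, led by RPS6A with 1.86 (SE 0.39) and RPL23AB with 1.74 (SE 0.37). Of 34 cell cycle and replication genes 24 rose and 1 fell, or 27 and 1 adjusted over the list alone; PCNA1, the sliding clamp of DNA polymerase, rose by 3.09 (SE 0.43) and the helicase gene MCM3 by 2.40 (SE 0.38). Of 6 stomatal lineage markers 5 rose, including EPF2 from 6.24 to 36.8 FPKM. Of 21 flavonoid genes 17 rose, with DFR, for dihydroflavonol reductase, going from 0.672 to 117 FPKM.

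Of 38 expansin and XTH genes tested, 14 rose and 10 fell. EXPA1 rose from 32.8 to 774 FPKM, and XTH15 (AT4G14130, chromosome 4, 8137051 to 8138281) fell from 1915 to 15.3 FPKM, a log2 fold of -6.97 (SE 0.49). Of 16 dark and shade induced genes 13 fell, or 14 adjusted over the list alone, with PIL1 at -3.95 (SE 0.56). Early auxin response genes divided into 8 up and 10 down of 34, with GH3.17 up by 2.59 (SE 0.43) and IAA20 down to 14.6 FPKM from 201. Auxin synthesis and transport genes divided into 4 up and 4 down of 17, with TAR2 up by 1.66 (SE 0.38) and YUC8 at -1.79 (SE 0.46). Gibberellin and brassinosteroid genes divided into 9 up and 6 down of 31, and GA2OX6 fell from 43.4 to 4.33 FPKM. The largest rise among named genes was that of NDA1, for an alternative NADH dehydrogenase, with 8.54 (SE 1.03).

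Of 31 light signalling genes 16 rose and 6 fell, or 17 and 7 adjusted over the list alone; PHYA, for the photoreceptor of dark-grown seedlings, fell from 291 to 42.2 FPKM. Clock genes divided into 6 up and 7 down of 21, or 6 and 8 adjusted over the list alone, with LHY at -1.52 (SE 0.36). Of 15 heat and stress genes 8 rose, or 9 adjusted over the list alone, including HSFA2 with 3.73 (SE 0.48). Of 18 ethylene and hook genes 9 fell and 1 rose, or 10 and 2 adjusted over the list alone, and HLS1 stood at -2.62 (SE 0.41). Of 7 seed storage and lipid genes 5 fell, or 6 adjusted over the list alone; ICL, for isocitrate lyase, fell from 3284 to 407 FPKM. Wounding, touch and jasmonate genes divided into 4 up and 4 down of 15, and 2 of 10 shoot meristem and leaf markers fell. PIF4 and PIF5 rose and PIF3 fell, and the 1 root marker tested was not called. In the authors' deposited table, 4575 genes rose and 3776 fell of 19057 tested. With centred folds and a normal p from the statistic the counts were 2219 and 1847.

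In hypocotyls, the first light comparison asked what changed within 1 h. Many photosynthesis and flavonoid genes rose, and part of the SAUR genes fell. SIG5 rose from 1.83 to 192 FPKM, a log2 fold of 6.72 (SE 0.46), and FLS1, for flavonol synthase, by 6.50 (SE 0.81). Of 66 SAUR genes tested, 29 fell and 0 rose in the authors' deposited table; at an unadjusted p under 0.05, 32 fell and 3 rose, and adjusted over the list alone 30 fell and 2 rose. SAUR11 fell from 73.6 to 6.88 FPKM and SAUR68 from 9.99 to 1.32 FPKM, and the median of the tested members was -0.85, at percentile 0, or -0.50 over all 78 members with a pseudocount of 1 FPKM.

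Of 52 photosynthesis genes 47 rose, or 49 adjusted over the list alone, with a median of 1.67; PSBS, for a photoprotective subunit, rose from 16.2 to 295 FPKM and LHCB1.1, a near copy, from 5.73 to 71.7 FPKM. Of 25 chlorophyll synthesis genes 13 rose, including CHLH with 3.88 (SE 0.40) and GUN4 with 3.54 (SE 0.46). Of 16 flavonoid genes 13 rose, or 15 adjusted over the list alone; CHS, for chalcone synthase, shares its locus with another gene and rose from 1.47 to 83.1 FPKM. Of 31 light signalling genes 21 rose and 3 fell, with ELIP1 up by 4.52 (SE 0.42) and PHYA at -0.78 (SE 0.41). Of 21 clock genes 12 rose, led by PRR9 with 3.28 (SE 0.41); adjusted over the list alone 1 also fell. Of 14 heat and stress genes 7 rose, or 8 adjusted over the list alone, with HSFA2 up by 4.45 (SE 0.47).

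Of 44 expansin and XTH genes 15 fell and 6 rose; EXPA12 fell from 35.1 to 4.49 FPKM and XTH32 rose from 6.7 to 60.4 FPKM. Of 33 early auxin response genes 11 fell and 2 rose, with GH3.3 at -2.54 (SE 0.40) and IAA28 up by 2.75 (SE 0.40). Of 17 auxin synthesis and transport genes 7 fell and 1 rose, or 8 and 1 adjusted over the list alone, and the exporter gene PIN4 rose from 17.7 to 80.2 FPKM. Gibberellin and brassinosteroid genes divided into 7 up and 8 down of 32, or 7 and 9 adjusted over the list alone: GA2OX1, for a gibberellin-inactivating enzyme, rose by 4.51 (SE 0.54), GA20OX1, for a gibberellin-forming enzyme, stood at -2.56 (SE 0.49), and PRE6 fell from 239 to 38.9 FPKM. Of 17 dark and shade induced genes 10 fell and 1 rose, with PIL1 at -3.16 (SE 0.49).

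Of the remaining lists, ethylene and hook genes had 3 of 20 members down, including ACS5 from 18.6 to 5.03 FPKM, and wounding, touch and jasmonate genes 4 of 15 up. Among 34 cell cycle genes 1 rose and 1 fell; adjusted over the list alone 1 rose and none fell, and 1 fell at an unadjusted p under 0.05. None of 28 ribosomal protein genes and none of 3 stomatal markers was called, and none had an unadjusted p under 0.05. Seed storage genes divided into 2 up and 2 down of 7; their median of -1.27 became 0.31 when members under 1 FPKM were left out. PIF5 rose, AS1 rose among 7 shoot markers, and 2 of 4 root markers, IRT1 and the near copy PHT1;1, rose to 1.83 and 7.79 FPKM. In the authors' deposited table, 1987 genes rose and 1019 fell of 19809 tested, so 66.1% of the calls were rises. With folds centred on the median gene and a normal p from the statistic the counts were 730 and 214, or 77.3% rises, and 12 SAUR genes fell; with the SE from the p-value the share of rises was 63.9%.

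By 6 h in hypocotyls, the question was which early changes lasted and which came later. Most flavonoid and photosynthesis genes were higher, and SAUR genes fell more often than they rose. CHS (AT5G13930, chromosome 5, 4488688 to 4495585) rose from 1.47 to 2815 FPKM, a log2 fold of 10.91 (SE 0.56), and FLS1 rose by 10.82 (SE 0.81). Of 65 SAUR genes tested, 36 fell and 8 rose, or 40 and 8 adjusted over the list alone. With centred folds 4 rose, and at a q-value under 0.01, 5 rose. The median of the tested members was -2.00 at percentile 0, and over all 78 members with a pseudocount of 1 FPKM it was -0.95. SAUR25 (AT4G13790, chromosome 4, 7999714 to 8000222) fell from 66.8 to 1.02 FPKM, a log2 fold of -6.03 (SE 0.92), and SAUR12 rose from 1.13 to 5.11 FPKM.

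Of 42 expansin and XTH genes 26 fell and 6 rose; EXPA12 (AT3G15370, chromosome 3, 5190572 to 5192077) fell by 7.76 on the log2 scale (SE 1.02), XTH19 fell from 320 to 7.44 FPKM, and XTH32 rose to 425 FPKM. Of 34 early auxin response genes 24 fell and 2 rose, or 25 and 2 adjusted over the list alone, with IAA6 falling from 93.2 to 1.1 FPKM. Of 17 auxin synthesis and transport genes 11 fell and 1 rose, or 12 and 1 adjusted over the list alone, including TAA1 at -2.53 (SE 0.45). Of 32 gibberellin and brassinosteroid genes 16 fell and 5 rose, or 16 and 6 adjusted over the list alone, with PRE1 at -4.21 (SE 0.69). Of 17 dark and shade induced genes 16 fell, including IAA19 from 268 to 14.8 FPKM. Of 34 cell cycle genes 14 fell and 2 rose, or 15 and 2 adjusted over the list alone; CDKB2;1, which shares its locus with another gene, stood at -1.30 (SE 0.38). Of 20 ethylene and hook genes 7 fell, with ACS5 at -5.11 (SE 0.63).

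Of 52 photosynthesis genes 50 rose and 1 fell, with a median of 3.16; LHCB1.5 and LHCB2.1, both near copies, rose to 2692 and 175 FPKM, and the member that fell was the near copy RBCS2B, from 35.3 to 20.6 FPKM. Of 25 chlorophyll synthesis genes 21 rose and 1 fell, or 22 and 1 adjusted over the list alone, with CHLG up by 3.97 (SE 0.48) and PORA at -4.42 (SE 0.58). Of 20 flavonoid genes 15 rose, with a median of 5.74, or 3.28 over all 21 members with a pseudocount of 1 FPKM. Of 14 heat and stress genes 12 rose, including HSP70 from 52.2 to 755 FPKM. Of 30 light signalling genes 16 rose and 5 fell, or 17 and 6 adjusted over the list alone, with HYH up by 4.74 (SE 0.50). Clock genes divided into 8 up and 6 down of 21, with ELF4 up from 42.8 to 703 FPKM. ASN1, for asparagine synthetase, fell from 175 to 0.868 FPKM.

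Of 28 ribosomal protein genes 5 rose and 1 fell, of 15 wounding, touch and jasmonate genes 1 rose and 7 fell, and of 7 seed storage genes 5 fell. AS1 and CUC1 rose among 9 shoot markers, the near copy PHT1;1 fell among 4 root markers, and neither of the 2 stomatal markers tested was called or had an unadjusted p under 0.05. PIF3 rose, and adjusted over the list alone 2 PIF genes rose. In the authors' deposited table, 3440 genes rose and 4365 fell of 19871 tested. The median gene with at least 1 FPKM stood at -0.119 in this table, and relative to it, with a normal p from the statistic, 2220 genes rose and 1653 fell, so that the share of rises went from 44.1% to 57.3%, or to 53.2% with the SE from the p-value; the SAUR median relative to it was -1.88.

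**Figure D2:**
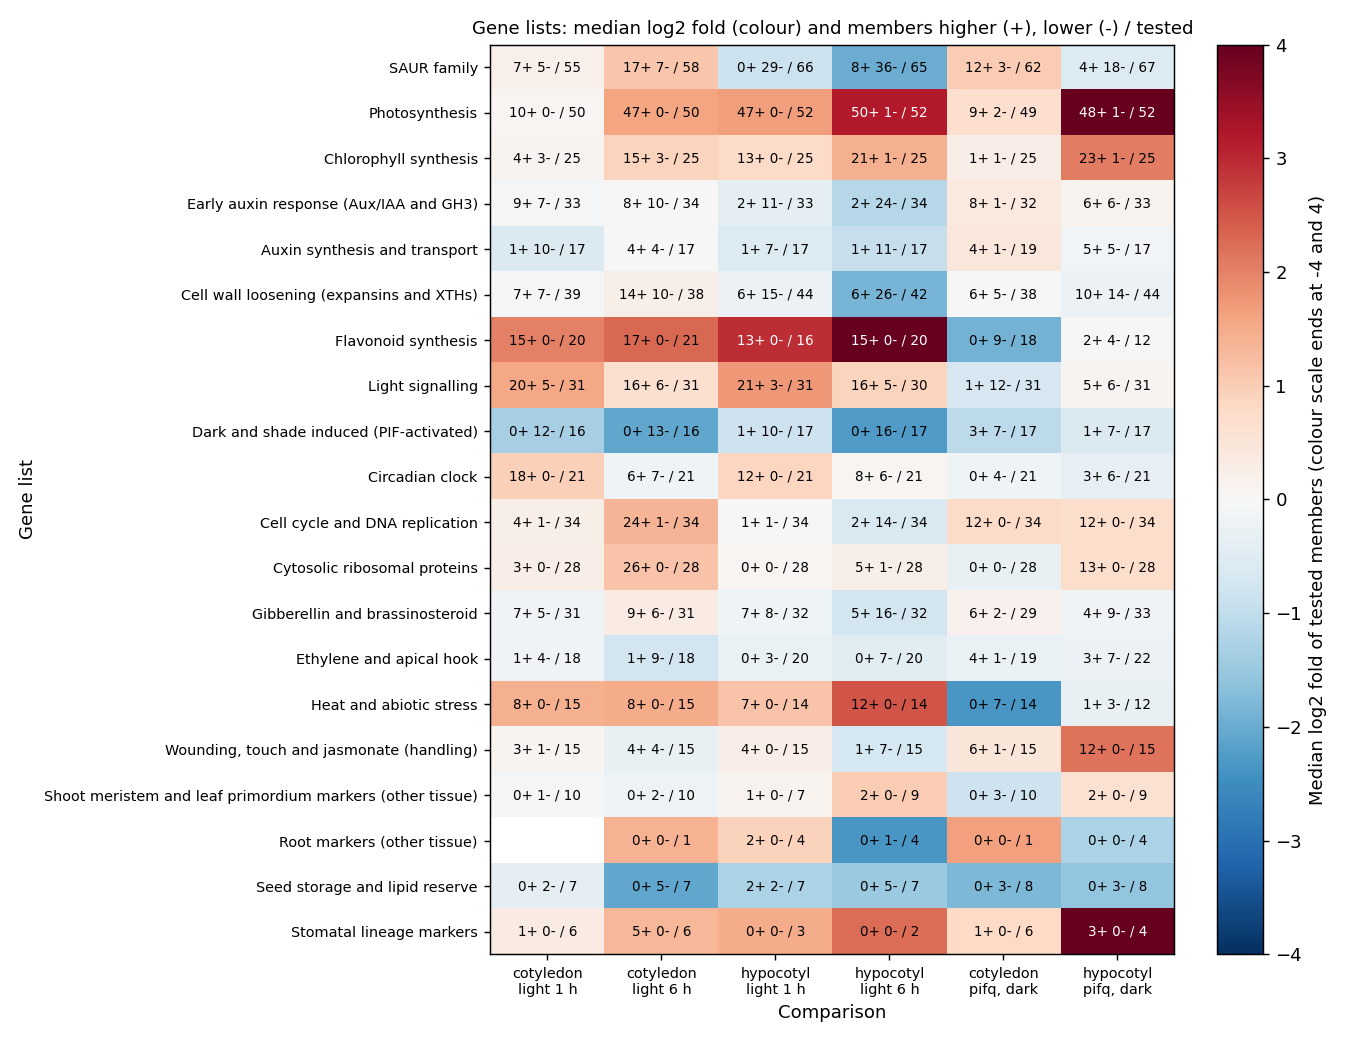
Colour gives the median log2 fold of the tested members of each gene list (rows) in each of the 6 comparisons (columns), and the text in each cell gives the members called higher and lower at the authors' deposited q-value under 0.05 and the members tested. The median of SAUR genes in hypocotyls was -2.00 at 6 h of light, and that of photosynthesis genes there was 3.16.

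Comparing the organs directly asked whether the same light changed a gene differently in each. After 6 h, SAUR16 was 5.64 (SE 0.69) up in cotyledons and stood at -3.47 (SE 0.51) in hypocotyls, a difference of 9.11 (SE 0.86, adjusted p 2.41e-23). SAUR50 (AT4G34760, chromosome 4, 16582183 to 16582879) rose to 261 FPKM in cotyledons, by 3.91 (SE 0.42), and fell from 206 to 32.4 FPKM in hypocotyls, a difference of 6.58 (SE 0.59). SAUR6 (AT2G21210, chromosome 2, 9085210 to 9085909) differed by 6.39 (SE 0.70), SAUR52 by 6.13 (SE 1.11), SAUR9 by 5.92 (SE 1.07) and the near copy SAUR62 by 8.06 (SE 1.46). Of 52 SAUR genes tested in both organs, 19 responded more positively in cotyledons and 2 less, or 22 and 3 adjusted over the list alone. At an adjusted p under 0.01 the counts were 16 and 0. The 19 genes include SAUR11 and SAUR4, which the authors' deposited tables called in neither organ. At 6 h the authors' deposited tables called 12 SAUR genes in opposite directions in the organs, of which SAUR40, named here after its values were seen, fell in cotyledons from 0.387 to 0 FPKM and rose in hypocotyls from 2.13 to 8.44 FPKM. At 1 h 3 of 48 SAUR genes responded more positively in cotyledons, or 6 above and 1 below adjusted over the list alone; SAUR6 differed by 3.51 (SE 0.68) and SAUR50 by 2.2 (SE 0.59, adjusted p 0.0446).

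**Figure D3:**
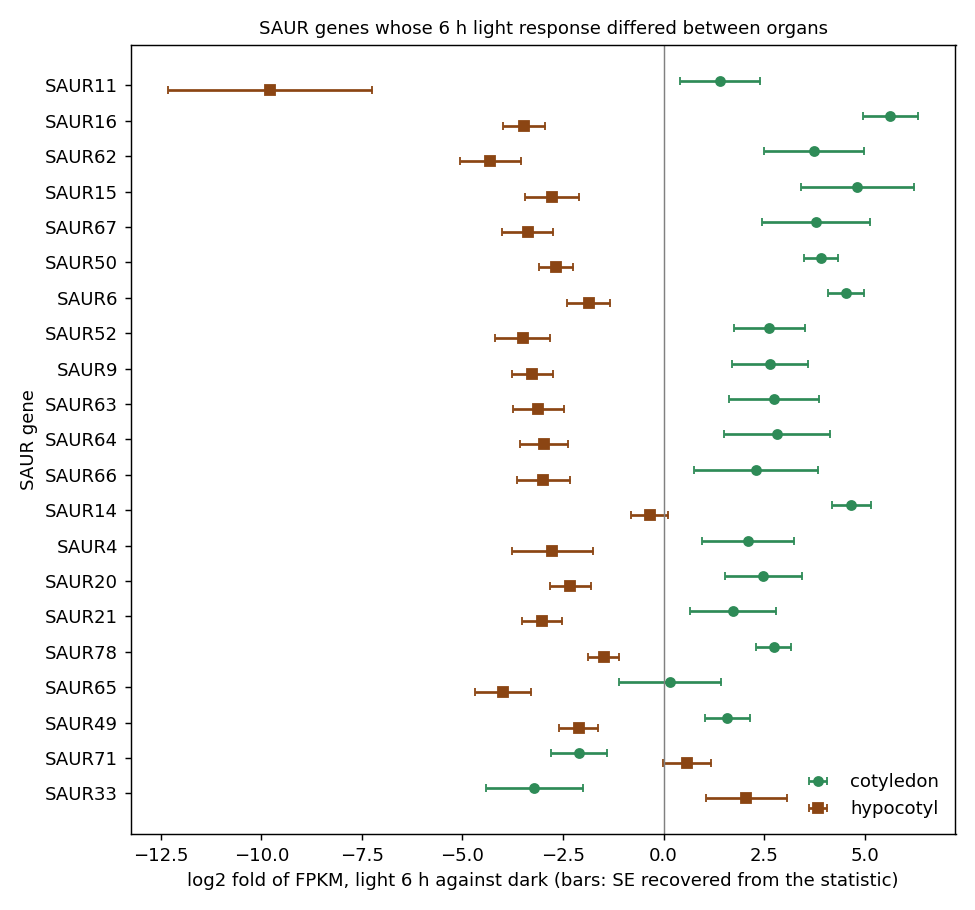
Points give the log2 fold of FPKM after 6 h of light against dark in cotyledons (green circles) and hypocotyls (brown squares) for the 21 SAUR genes whose response differed between organs, with bars for the SE recovered from the authors' statistic. In 19 of them the cotyledon fold lies above the hypocotyl fold, and SAUR71 and SAUR33 show the opposite order. SAUR71 and SAUR33 did not differ at an adjusted p under 0.01, and SAUR11 and SAUR4 were called in neither organ.

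Of 37 expansin and XTH genes 20 responded more positively in cotyledons at 6 h and 4 less, or 21 and 4 adjusted over the list alone. The cell cycle list had 17 of 34 above, or 23 adjusted over the list alone, with a median difference of 2.14. Of 31 early auxin response genes 10 did, or 12 adjusted over the list alone, and of 30 gibberellin and brassinosteroid genes 8 did and 3 were below, while of 15 auxin synthesis and transport genes 3 did and 1 was below, or 4 and 2 adjusted over the list alone. Of 50 photosynthesis genes 1 was above and 18 were below, or 1 and 26 adjusted over the list alone. Flavonoid genes had 8 of 20 below, or 9 adjusted over the list alone; CHS differed by -8.94 (SE 0.76). The arabinogalactan protein gene AGP21 went from 56.8 to 1421 FPKM in cotyledons and from 1481 to 237 FPKM in hypocotyls. At 1 h the bHLH gene PRE6 fell in hypocotyls, with a difference between organs of 2.99 (SE 0.52), and CIA2, for chloroplast protein import, rose in hypocotyls alone by the authors' calls, with a difference of -3.66 (SE 0.55).

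Over all genes, 1202 of 18153 responded more positively in cotyledons at 6 h and 1087 less; with folds centred on the median gene of each table the counts were 1023 and 1387. At 1 h the counts were 25 and 58 of 18089, and with the SE recovered from the deposited p-value 132 and 230. The authors' deposited tables called 948 genes in opposite directions at 6 h and 56 at 1 h, and in the same direction in both organs 3080 at 6 h and 1396 at 1 h. If calls were independent between organs, 806 shared rises and 776 shared falls would be expected at 6 h, against 1709 and 1371 found. The number of opposite calls expected in that case was not computed, so 948 cannot be read as many or few.

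The line labelled pifq was compared with wild type in the dark to ask which dark-state expression depends on the PIF factors. PIF3 (AT1G09530, chromosome 1, 3076582 to 3079539) fell from 64.7 to 0.623 FPKM in cotyledons, a log2 fold of -6.70 (SE 0.47), and from 37.6 to 2.16 FPKM in hypocotyls, a log2 fold of -4.12 (SE 0.35). PIF5 (AT3G59060, chromosome 3, 21827978 to 21830507) fell in hypocotyls from 21.5 to 8.66 FPKM and stood at 15.8 and 13.8 FPKM in cotyledons, a q-value of 0.892 in the authors' deposited table. PIF1 (AT2G20180, chromosome 2, 8701013 to 8706900), which shares its locus with another gene, stood at 36.9 and 30.5 FPKM in cotyledons and at 35.4 and 55.4 FPKM in hypocotyls, q-values of 0.782 and 0.0833 in the authors' deposited table. PIF4 (AT2G43010, chromosome 2, 17886427 to 17889050) rose from 15.4 to 45 FPKM in cotyledons and from 19.3 to 44.9 FPKM in hypocotyls. Adjusted over the list alone, 2 of the 4 PIF genes rose and 2 fell in hypocotyls. The labels do not give the alleles, and an insertion can leave RNA of a gene, so these levels describe transcripts and not function.

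In cotyledons of the pifq-labelled line, some genes that respond early to light were lower than in wild type, while others were higher. ELIP1 (AT3G22840, chromosome 3, 8084447 to 8085560), for an early light-induced protein, fell from 632 to 0.584 FPKM, a log2 fold of -10.08 (SE 0.64), and ELIP2 from 1138 to 3.2 FPKM. Of 62 SAUR genes tested 12 rose, 3 fell and 47 were not called, or 14 rose and 3 fell adjusted over the list alone, with a median of the tested members of 1.01 at percentile 100; over all 78 members with a pseudocount of 1 FPKM it was 0.38. SAUR14, named here after its values were seen, rose from 14 to 65.6 FPKM, the near copies SAUR63 and SAUR67 rose to 6.38 and 3.88 FPKM, and SAUR17 fell from 151 to 6.63 FPKM. QQS and the lipoxygenase gene LOX2 rose by 7.06 (SE 0.74) and 6.37 (SE 0.62).

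Of 31 light signalling genes 12 fell and 1 rose in the pifq-labelled cotyledons, or 13 and 1 adjusted over the list alone, with BBX23 at -6.99 (SE 0.78). Of 18 flavonoid genes 9 fell, or 11 adjusted over the list alone; the anthocyanin regulator MYB75 fell from 31.7 to 0.486 FPKM. Of 14 heat and stress genes 7 fell, or 11 down and 1 up adjusted over the list alone, including HSP22 at -6.17 (SE 0.90). Of 17 dark and shade induced genes 7 fell and 3 rose, or 9 and 3 adjusted over the list alone: HFR1 and PIL1 stood at -5.70 (SE 0.46) and -5.88 (SE 0.63), and the auxin synthesis gene YUC9 rose from 0.0379 to 4.64 FPKM. Of 32 early auxin response genes 8 rose and 1 fell, or 9 and 2 adjusted over the list alone, with GH3.3 up by 3.69 (SE 0.43). Of 19 auxin synthesis and transport genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone.

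Photosynthesis genes divided into 9 up and 2 down of 49 in these cotyledons, or 13 and 3 adjusted over the list alone; the near copy LHCB1.4 rose from 414 to 8367 FPKM and RBCS1B fell from 6926 to 1565 FPKM. Of 25 chlorophyll synthesis genes CAO rose and PORA fell. Of 34 cell cycle genes 12 rose, or 13 adjusted over the list alone, with CYCB2;2 up by 1.93 (SE 0.55). Expansin and XTH genes had 6 up and 5 down of 38, or 9 and 5 adjusted over the list alone; XTH19 rose by 2.69 (SE 0.36) and XTH15 fell from 2223 to 92.8 FPKM. Gibberellin and brassinosteroid genes had 6 up and 2 down of 29, or 7 and 2 adjusted over the list alone, with PRE1 up from 1.24 to 12.2 FPKM and GA3OX1 at -2.42 (SE 0.40). Wounding, touch and jasmonate genes had 6 up and 1 down of 15, or 7 and 3 adjusted over the list alone, with WRKY40, which shares its locus, up by 3.37 (SE 0.48).

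Ethylene and hook genes had 4 up and 1 down of 19, or 4 and 3 adjusted over the list alone, with ACO4 up by 2.11 (SE 0.36). Of 21 clock genes 4 fell, or 5 down and 1 up adjusted over the list alone, with ELF4 at -2.54 (SE 0.45). Of 8 seed storage and lipid genes 3 fell, or 5 adjusted over the list alone, with ICL at -3.25 (SE 0.77). Of 10 shoot meristem and leaf markers 3 fell, or 5 adjusted over the list alone, with STM from 9.88 to 2.93 FPKM, and FAMA rose among 6 stomatal markers. None of 28 ribosomal protein genes was called, and 1 fell at an unadjusted p under 0.05; the 1 root marker tested was not called. In the authors' deposited table, 934 genes rose and 1105 fell of 19516 tested, and at a q-value under 0.01, 607 rose.

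In hypocotyls of the pifq-labelled line, photosynthesis and chlorophyll synthesis genes were higher in the dark. Of 52 photosynthesis genes 48 rose and 1 fell, both over all genes and adjusted over the list alone, with a median of 4.17; LHCB1.4 (AT2G34430, chromosome 2, 14524756 to 14525763), a near copy, rose from 4.44 to 2518 FPKM. Of 25 chlorophyll synthesis genes 23 rose and 1 fell, with CHLH up by 4.43 (SE 0.31), GUN4 by 4.34 (SE 0.36) and PORA at -1.58 (SE 0.34). Of 67 SAUR genes tested 18 fell, 4 rose and 45 were not called, or 19 fell and 4 rose adjusted over the list alone, with a median of -0.56 at percentile 0. SAUR25 fell by 2.72 on the log2 scale (SE 0.39), and SAUR12 rose from 1.23 to 20.7 FPKM.

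Of 15 wounding, touch and jasmonate genes 12 rose, or 14 adjusted over the list alone, with a median of 2.17, including LOX3 from 1.04 to 37.3 FPKM and JAZ7 from 7.1 to 91.2 FPKM. The median of this list in the pifq-labelled cotyledon was 0.47. The list was fixed to cover handling of samples too, and unlike handling of the pifq-labelled hypocotyls was not tested. Some shoot and stomatal markers were also higher there: STM rose from 0.702 to 4.14 FPKM and FIL from 0.677 to 2.18 FPKM among 9 shoot markers, and 3 of 4 stomatal markers rose, or 4 adjusted over the list alone, with FAMA from 0.0117 to 1.31 FPKM. Of 28 ribosomal protein genes 13 rose, or 17 adjusted over the list alone, with RPS6A up by 1.57 (SE 0.27). Cell cycle genes had 12 of 34 up, or 15 adjusted over the list alone, with CYCD3;2 up by 1.68 (SE 0.35). None of 4 root markers was called, and 1 fell at an unadjusted p under 0.05.

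Expansin and XTH genes had 10 up and 14 down of 44 in these hypocotyls. EXPA9 fell from 393 to 6.39 FPKM, EXPA12 stood at -8.24 (SE 1.00), TCH4 rose from 65 to 337 FPKM, and XTH6 (AT5G65730, chromosome 5, 26299032 to 26300478) rose from 0.0124 to 65.1 FPKM with a log2 fold of 12.35 whose SE was 2.45. Gibberellin and brassinosteroid genes had 4 up and 9 down of 33, or 5 and 9 adjusted over the list alone, with GA3OX1 from 68 to 3.16 FPKM. Of 17 dark and shade induced genes 7 fell and 1 rose, or 9 and 1 adjusted over the list alone, with HFR1 from 178 to 8.56 FPKM. Ethylene and hook genes had 3 up and 7 down of 22, with ACS5 at -3.73 (SE 0.36). Early auxin response genes had 6 up and 6 down of 33, with GH3.6 up by 1.29 (SE 0.28) and IAA28 at -2.23 (SE 0.33), and auxin synthesis and transport genes 5 up and 5 down of 17, with LAX1 up by 2.19 (SE 0.29) and YUC5 at -3.90 (SE 0.77).

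Of 31 light signalling genes 5 rose and 6 fell, with ELIP1 at -5.82 (SE 0.63). Flavonoid genes had 2 up and 4 down of 12, with UGT78D1 up by 3.42 (SE 0.42) and CHS at -3.91 (SE 0.88). Clock genes had 3 up and 6 down of 21, with RVE2 from 89.6 to 21.7 FPKM. Heat and stress genes had 1 up and 3 down of 12, with HSFA7A at -1.43 (SE 0.28), and 3 of 8 seed storage genes fell, or 4 adjusted over the list alone. In the authors' deposited table, 2651 genes rose and 2962 fell of 20441 tested.

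Between organs, the effect of the pifq-labelled line differed in both directions. Among SAUR genes that differed, more again stood higher in cotyledons than in hypocotyls relative to wild type, with 19 of 56 above and 2 below, or 21 and 3 adjusted over the list alone, and a median difference of 1.67. Photosynthesis genes had 46 of 49 below, or 47 adjusted over the list alone, with a median difference of -3.46. AZI1, a defence-priming gene, rose in cotyledons and fell from 599 to 17.5 FPKM in hypocotyls, a difference of 6.44 (SE 0.48). The desaturase gene AT1G06360 fell in cotyledons from 179 to 72.9 FPKM and rose in hypocotyls from 11.1 to 91.5 FPKM. In all, 829 of 18582 genes were above and 1296 below.

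The last comparison asked how far the pifq-labelled line in the dark shared the changes that 6 h of light made in wild type. In hypocotyls the authors' deposited tables called 1174 genes higher in both and 1420 lower in both, against 428 and 657 if calls were independent, and 585 in opposite directions of 19596 tested. In cotyledons 503 were higher in both and 675 lower in both, against 210 and 220, and 212 went in opposite directions of 18804. For opposite calls the number expected under independence was not computed. EXPA12 and ACS5 fell and GUN4 rose in both hypocotyl comparisons, while XTH15 and PORA fell in both cotyledon comparisons. ELIP1 rose in hypocotyls with light and fell in the pifq-labelled line. Both comparisons appear to use the same dark wild type samples, which by itself makes folds correlate. The covariance that a shared control gives was taken from 100 simulations of unchanged groups. Among genes with at least 5 FPKM, a filter chosen after the values over all genes were seen, the correlation of the folds was 0.48 in hypocotyls against 0.44 simulated and 0.43 in cotyledons against 0.35. The simulated groups held noise alone, so their correlation follows from the share of noise set for the dark samples. It cannot be weighed against the observed correlation, whereas the covariances are on one scale. The covariance of the folds was 0.584 in hypocotyls against 0.110 simulated and 0.374 in cotyledons against 0.159. Over all tested genes it was 0.742 against 0.308 in hypocotyls and 0.528 against 1.656 in cotyledons.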

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

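Of the tests in this part, the values expected without a change, those over all 83 tested members and the test on cotyledon tissue at the share the photosynthesis genes would need were chosen after the result was seen, and the rule for reading the test on near copies of SAUR genes was reworded after its value was seen, while the bound it had to pass stayed as it was. The differences between organs below are cotyledon minus hypocotyl log2 folds that passed the test of the difference itself and that the rule for named genes picked.

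Some SAUR genes stood out because their light response differed between the organs. At 1 h the differences were 3.51 for SAUR6 and 2.2 for SAUR50. At 6 h they were 9.11 for SAUR16, 8.06 for the near copy SAUR62, 6.58 for SAUR50, 6.39 for SAUR6, 6.13 for SAUR52 and 5.92 for SAUR9.

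Other genes differed in their 1 h response between organs. AT1G55960, for a lipid transport family protein, differed by 3.81, AT4G29905 by 3.63 and PRE6 by 2.99, all more positive in cotyledons. UGT84A2, for a glycosyltransferase, differed by -3.72, PMI1, needed for chloroplast movement, by -3.76 and CIA2 by -3.66. The snoRNA gene AT4G39366, a near copy, differed by 1.2 and AT3G01940 by -2.13, but neither was called in any organ by the authors' deposited tables, and their recovered cotyledon SEs of 0.01 and 0.08 lay far below the median of 0.39.

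At 6 h, AGP21 differed by 7.29, CHS by -8.94, the near copy KIN1 by -8.15, DAA1 by -5.97 and UGT84A2 by -5.74. MIR171b differed by 5.33, AT4G39366 by 7.38 and AT4G37095 by 9.36; the authors' deposited tables called none of these 3 genes in either organ, and their recovered cotyledon SEs of at most 0.01 make the differences uncertain.

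The effect of the pifq-labelled line differed by 6.44 for AZI1, 5.55 for CAX3, 5.85 for AT3G54830 and 6.52 for AT5G02540, all more positive in cotyledons. It differed by -5.23 for AT5G20740, -4.95 for AT1G60060, -5.73 for AT5G44440 and -4.33 for AT1G06360.

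The rise of part of the SAUR genes in cotyledons beside the fall of many in hypocotyls after 6 h was weighed against 3 technical explanations. Hypocotyl tissue carried into the light-treated cotyledon samples would raise all hypocotyl-enriched transcripts. The 472 such genes outside the family had a median cotyledon log2 fold of -0.29 (quartiles -1.39 and 0.84), with 114 called higher. The 22 hypocotyl-enriched SAUR genes had a median of 2.02, but most of them were not called in cotyledons at 6 h. Enrichment was read across tables that may differ in scale. The SAUR median difference of 2.73 stood at percentile 100 of random lists matched on transcript length. Those lengths came from an annotation other than the authors' gene models, and that of SAUR17, 580 bases, was longer than its span given above. Short transcripts in the authors' models were therefore not tested. The values argue against near copies as the sole cause, since 47 members without one had a median difference of 2.36, with 15 of them above and 2 below. The 5 members with a near copy had a median of 5.86. Reads shared over shorter stretches, which the definition of a near copy leaves out, were not tested. A different regulation of SAUR genes by light in each organ, the organ being part of the design, may account for the pattern. The SAUR list and the naming of SAUR genes called in opposite directions were fixed before the data were examined. The direction of the pattern was read from these data, and no other data tested it. Transcript length and reads shared over shorter stretches stay open beside a different regulation in each organ.

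The higher photosynthesis transcripts in the pifq-labelled dark hypocotyl were weighed against cotyledon tissue in those samples and against near copies. Cotyledon-enriched genes that light did not raise in hypocotyls, 81 in number and 30 of them on organelle genomes, stood at a median of 11.7% of their cotyledon level, against 1.97% in wild type, and the 45 raised photosynthesis genes stood at 19.5%, so some carried-over tissue cannot be told apart from a change within the hypocotyl by this test; these shares set FPKM of separate tables side by side, which may differ in scale. At the share the photosynthesis genes would need, abundant nuclear cotyledon genes argue against carried-over cotyledon. The 24 such genes stood at a median of 2.68% (quartiles 1.42 and 12.35). AT3G05730 stood at 0.554 FPKM against 1416 FPKM, CA2 at 10.4 FPKM against 2147 FPKM and PORA at 5.65 FPKM against 599 FPKM. GASA6 at 120 FPKM against 803 FPKM and AT5G44440 at 213 FPKM against 495 FPKM stood higher. Carried-over cotyledon would add the same share of every cotyledon transcript, so the genes of lowest share limit it most. The tables argue against near copies as the sole cause, since 43 members without one had a median log2 fold of 3.94, against 6.13 for members with one. A smaller share of cotyledon stays open, but would account for only a part of the photosynthesis level. Other tissue, such as the shoot apex, stays open beside an effect of the mutations. The shoot meristem marker STM rose by 2.56 on the log2 scale in the pifq-labelled hypocotyl. It stood at -1.75 in the pifq-labelled cotyledon, so the wild type cotyledon samples held STM transcripts as well. An unlike share of the apex between the organ samples was not tested. FAMA, a stomatal lineage marker, rose by 6.81 in the pifq-labelled hypocotyl and by 1.52 in the cotyledon.

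Lower transcripts of some early light-induced and heat-shock genes in the pifq-labelled dark cotyledon were weighed against light reaching the wild type samples at harvest and against the wild type columns of that table. The 308 genes raised at least 4-fold within 1 h of light had a median of -0.38 (quartiles -1.36 and 0.57), with 66 down and 37 up, so light at harvest cannot be told apart from an effect of the mutations. In the same cotyledons 381 genes raised at least 4-fold at 6 h and not called at 1 h had a median of 1.09. In the pifq-labelled hypocotyl, 415 genes raised at least 4-fold at 1 h in hypocotyls had a median of 0.90, with 51 down and 172 up. Error in dark samples shared by both folds raises such medians by itself. If all error lay there, they would stand without a change at 1.36 for the 308 genes, 0.64 for the 381 and 2.07 for the 415. The median of 1.09 therefore decides little. The median of -0.38 had the opposite sign to such a shift and stood at percentile 0 of random lists matched on FPKM. The median of 0.90 lay below 2.07, but that value assumes that all error lay in dark samples. The median of 0.90 therefore decides little too. The tables argue against unlike wild type columns, since 0.187% of 12325 genes lay over 2-fold apart between them, and the 32 members called lower of the flavonoid, light signalling, heat and clock lists had a median of -2.35 against the dark columns of the light tables and -2.53 against their own column (-0.67 and -0.95 over all 83 tested members).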

How the results depend on the processing

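The settings were chosen before the data were examined except centred folds with the SE from p, genes with a locus of their own and SAUR genes without near copies, which were added after seeing the data. No paired analysis was possible because the authors deposited 1 value per group; leave-one-out, a replicate block and a pseudocount per replicate were not run for the same reason. Counts of genes and of SAUR genes stayed within 1.5 times under at least 1 FPKM, under a locus of their own and, for SAUR genes, without near copies. With centred folds and the SE from p, all 12 gene counts did too. Of the named folds, 382 stayed on their side of the threshold with centred folds, 58 no longer passed and 11 newly passed; none of them turned direction. With a pseudocount of 1 FPKM, 284 stayed and 167 moved. With it and all members of a list, 19 list medians moved and 103 stayed within the median SE of the members. Among those moved were SAUR genes in hypocotyls at 6 h, from -2.00 to -0.95, and flavonoid genes there, from 5.74 to 3.28; the cause was not tested. The unknown depth per sample limits all of this.

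With centred folds, genes up and down were 664 and 372 in cotyledons at 1 h, 2219 and 1847 at 6 h, 730 and 214 in hypocotyls at 1 h, and 2220 and 1653 at 6 h. SAUR genes up in cotyledons at 1 h were 3, down in hypocotyls at 1 h 12 and up in hypocotyls at 6 h 4. With a normal p from the statistic the gene counts were 684 and 354, 2385 and 1723, 759 and 199, and 1910 and 1968 in the same order, and the SAUR counts 3, 12 and 4. Both settings replace the deposited p of the light tables by a larger one, which lowers the counts by construction.

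At q under 0.01, genes down were 1018 in cotyledons and 625 in hypocotyls at 1 h, genes up in the pifq-labelled cotyledon 607, SAUR genes down in cotyledons at 1 h 3 and SAUR genes up in hypocotyls at 6 h 5. With at least 2-fold, genes up and down were 1120 and 686 in cotyledons at 1 h and 2821 and 2319 at 6 h, genes down in hypocotyls 455 at 1 h and 2504 at 6 h, and shared hypocotyl calls 1686. A stricter threshold lowers counts by construction. Adjusted over the list alone, 2 SAUR genes rose in hypocotyls at 1 h.

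Genes that differed between organs with the SE from p were 362 at 1 h and 5046 at 6 h, with 7 SAUR genes at 1 h; this SE is smaller in the light tables. At an adjusted p under 0.01 they were 44 at 1 h, 1405 at 6 h and 1361 in the pifq-labelled line. The median of seed storage and lipid genes in hypocotyls at 1 h turned from -1.27 to 0.31 with at least 1 FPKM; fewer members enter, and the cause was not tested.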

Other observations

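Genes of the chloroplast genome were examined after the values were seen, and no test of an explanation was chosen for them. In the pifq-labelled dark hypocotyl 55 of 85 chloroplast genes rose by the authors' deposited table, with a median log2 fold of 1.77, while in the pifq-labelled cotyledon 7 rose and 5 fell of 90. After 6 h of light 7 rose and 2 fell of 66 in hypocotyls, and 1 rose and 14 fell of 71 in cotyledons, where the median was -0.24. Of the genes of the mitochondrial genome, 11 of 81 fell and 2 rose in the pifq-labelled hypocotyl and 4 of 69 fell in the cotyledon, with medians of -0.84 and -0.85; neither group was tested against other genes.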
